A study of Escherichia coli with 2 samples.

How the data were processed

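RNA from biofilm cells of 1 wild-type and 1 ymgB mutant culture of E. coli BW25113, taken at 24 h, was measured on 1 array each. Per the labels' protocols, cells were broken by bead beating, RNA was purified on columns with DNase digestion on the column, poly-A control RNAs were added to the reverse transcription, and the fragmented cDNA was end-labelled with biotin. The labels name no further replicate, batch or scan date, so that culture, RNA preparation and array cannot be separated from strain.

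The deposited values are linear signal intensities per probe set. The authors computed them with MAS5, per the submitters' processing notes; the version and the settings are not given in the sources used here. MAS5 summarises perfect-match and mismatch probes into 1 signal and can scale each array to a common mean. In the deposited intensity values the mean over the probe sets between the 2nd and 98th percentiles was 499.8 on the wild-type array and 499.9 on the mutant array, so that both arrays were scaled to the same trimmed mean. Such a scale is set by whatever fills most probe sets, and a difference in the spread of signals between arrays then becomes a ratio that depends on signal. The SD over all probe sets was 1340 in the wild type and 655 in the mutant. Scanner files, detection calls and probe-level data were not used here. The signals ran from 0 to 28417.6, and only 1 value was 0. With 1 array per strain, the number of arrays limits the precision.

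Probe sets were named through the platform's annotation table and a gene table of the MG1655 assembly ASM584v2. Of 7312 probe sets, 4398 were in the platform table: 1543 with 1 entry, 2261 with several entries of 1 symbol, mostly the same gene in other strains, and 594 with several symbols. A probe set was named where its entries held exactly 1 K-12 gene, by gene number. This named 4286 probe sets for 4185 genes; 42 had several K-12 genes and 70 none and were left unnamed. The locus number in the probe set's own identifier was the same in 4101 cases. For the other 185 it differed or was absent, as for csrB, whose probe set is that of an intergenic region. Of 78 genes with several probe sets, the one with the highest mean signal was used, and none of these genes had probe sets whose log2 ratios differed by more than 1. No build is stated for the array design, so no coordinates are printed.

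Before the data were examined, the design fixed the following. The deposited scale was kept. Signals under a floor, the median of all probe sets except controls pooled over both arrays (421.6), were raised to it; a gene was measured if either array reached the floor, and a ratio with 1 array under it is a bound ("at least"). The log2 ratio is mutant over wild type. The size threshold was 2-fold. Without replicates no test of single genes was made. Beforehand, 25 gene lists were written from textbook knowledge: the ymg locus, acid resistance, curli, exopolysaccharide, type 1 fimbriae and Ag43, flagella and chemotaxis, biofilm regulators and AI-2, indole and tryptophan, RpoS-dependent general stress, oxidative stress, heat shock, cold shock, SOS response, ribosomal proteins, ATP synthase and aerobic respiration, TCA cycle, anaerobic respiration and fermentation, alternative carbon uptake and catabolism, iron acquisition, phosphate starvation, sulfate assimilation, amino acid synthesis, nucleotide synthesis, phage shock, and the BW25113 deletions. For each list with at least 4 measured members, the median log2 ratio was ranked among 10000 random lists of the same size, matched on mean log2 signal in 10 bins; a percentile under 2.5 or over 97.5 was called apart. Genes of an operon are transcribed together and are not independent, so the percentiles describe these arrays and are not p-values. The samples were pure cultures, so no list of other cell types was used.

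The rule for genes named in the text was: the ymg locus, the 12 highest and 12 lowest ratios past 2-fold among genes over the floor on both arrays (only 3 were higher), up to 5 bounds each way past 2-fold, up to 4 members of each list with the largest absolute ratio, and all deleted genes of the strain. cadA, apaG and rpsJ fall outside this rule and were named after their values were seen. The alternatives fixed beforehand were median centring, quantile normalization, a loess correction (fraction 0.3) of ratio on mean signal, floors at the 25th and 75th percentiles, no floor (0.1 as the lowest value), both arrays over the floor, the mean over probe sets of a gene, thresholds of 1.5-fold and 3-fold, unmatched random lists, and lists without their most extreme member. Subtraction of each array's median intergenic signal, with or without scaling of the mutant array on the 12 poly-A control probe sets (the poly-A scale), with the floor at the 75th percentile after it, was added after seeing the data.

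The calculation was tested on simulated data made from the wild-type array with log-normal noise. Of 200 genes changed 4-fold, 200 were recovered among 2804 measured genes, with 0 others called. A list of genes shifted together came out at percentile 100, and 4 of 50 unshifted lists were called apart. The changed genes were drawn from those far over the floor, and the noise was small beside the 2-fold threshold. Recovery and the lack of other calls thus followed from the settings. The simulation had no ratio that depends on signal, so it checks the calculation and not false calls on the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.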

Results

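Transcript levels were measured on Affymetrix expression arrays in biofilm cells of Escherichia coli BW25113, a K-12 laboratory strain, and of its ymgB mutant. Both strains had grown for 24 h as biofilms on glass wool in a medium labelled LBglu. There was 1 array for each strain. No value below has a replicate error, no p-value was computed across genes, and every difference describes these 2 arrays. Each array reported a signal for 7312 probe sets, covering genes, intergenic regions and controls. The median signal was 403 on the wild-type array and 438 on the mutant array. A gene counted as measured where at least 1 array reached a signal of 421.6, the median of all probe sets other than controls. Of 4185 K-12 genes with a probe set, 2967 were measured, 2256 of them on both arrays. A gene was called higher or lower where the signals differed by at least 2-fold, a rule of size and not a test.

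The deleted gene was examined first. The ymgB probe set read 3738.5 in the wild type and 4.6 in the mutant, so that ymgB (also named ariR, locus b1166) was at least 8.87-fold lower in the mutant. The other measured genes of the ymg locus had higher signals in the mutant. ycgZ (b1164), the first gene of the ycgZ-ymgA-ymgB-ymgC cluster, read 3022.7 in the wild type and 5746.9 in the mutant, a ratio of 1.90. ymgA, the gene before ymgB, read 4666.1 and 5346.9, a ratio of 1.15 that moved to log2 ratios of 0.89 after loess, 0.75 after quantile normalization and 1.43 on the scale set by the added poly-A control RNAs, against 0.20 as deposited. ymgC, which follows ymgB, read 376.1 and 570.3, at least 1.35-fold higher, and bluR, the repressor of this cluster, read 402.4 and 551, at least 1.31-fold higher. None of these 4 genes reached 2-fold on the deposited scale. ycgZ passed it after loess or quantile normalization, with log2 ratios of 1.55 and 1.57. Over the 5 measured members, ymgB included, the median log2 ratio (mutant over wild type) was 0.39, at percentile 99.7 of 10000 random gene lists matched on signal. Without ymgB it was 0.41, at percentile 99.7. Of the 5 members 3 were bounds: ymgB, ymgC and bluR, the last being the median gene. ymgC and bluR were measured only through the mutant array, so their ratios could not lie below 1. Under 3 alternatives fewer than 4 members were measured, so the list had no percentile. These were both arrays over the floor, the higher floor, and the intergenic median subtracted without poly-A scaling. On the scale set by the poly-A control RNAs described below, the list no longer stood apart (median 0.32, percentile 50.8). bluF, the light-responsive partner of BluR, was not measured.

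The comparison between the strains addresses which transcripts of biofilm cells differ when ymgB is lost. On the deposited scale 3 genes were at least 2-fold higher in the mutant and 59, ymgB included, were at least 2-fold lower. The 59 lower genes comprised 45 protein-coding genes, 11 rRNA genes, 1 tRNA gene, the small RNA ssrS and the transfer-messenger RNA ssrA. The genes of strong signal carried this excess: 53 of the 59 were among the 297 genes with the highest mean signal, where the median log2 ratio was -0.42, against -0.0030 over all measured genes. All 12 probe sets of the poly-A control RNAs, which were added at reverse transcription, were also lower on the mutant array. Their median log2 ratio was -1.23 ± 0.24 (SD over 12 probe sets), or 2.35-fold. These probe sets cover the Dap, Lys, Phe and Thr RNAs, several each, so that they are not independent observations. The SD does not measure the error of the amount added or of the array scale. After a loess correction for mean signal the counts were 10 higher and 8 lower, and after quantile normalization 9 higher and 10 lower. Directions below are relative to the deposited scale. When each array's median intergenic signal was subtracted and the mutant array was scaled on the poly-A controls, the median log2 ratio of all measured genes moved to 0.59, and 381 genes were higher and 4 lower. On this scale, called the poly-A scale below, 1 factor raises the mutant array after the subtraction, and the floor is set anew. Log2 ratios moved by unequal amounts, for csrB from 1.62 to 3.04 and for yodC from -2.12 to -1.90. Some genes near the floor moved down, as ymgC from 0.44 to 0.32 and bluR from 0.39 to 0.18. Because the factor raises the mutant array, a sign that turns on this scale is no evidence on a gene or list by itself.

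**Figure D1:**
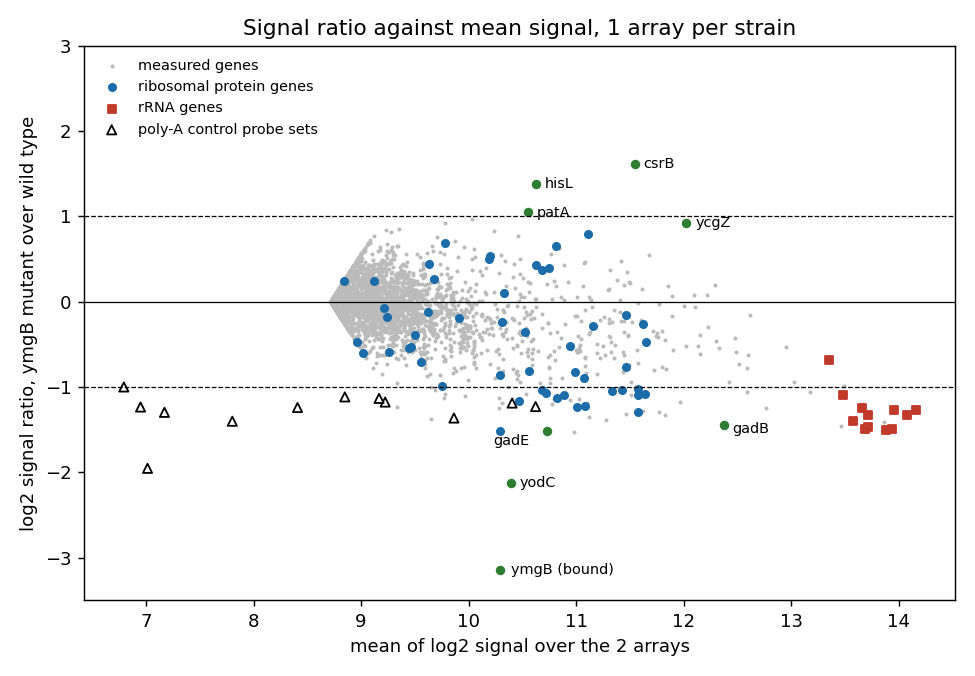
The log2 signal ratio (ymgB mutant over wild type, vertical axis) is plotted against the mean log2 signal of the 2 arrays (horizontal axis) for the 2967 measured genes, with signals under 421.6 raised to it, and for the 12 poly-A control probe sets at their own signals; dashed lines mark 2-fold. The rRNA genes and the poly-A controls lie mostly below the lower dashed line, csrB, hisL and patA lie above the upper one, and ribosomal protein genes lie on both sides of 0.

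The 3 genes higher by at least 2-fold were csrB, hisL and patA. csrB, a small RNA that sequesters the carbon storage regulator CsrA, read 1703.3 in the wild type and 5230.1 in the mutant, a ratio of 3.07. hisL, the leader peptide gene of the histidine operon, read 981.2 and 2554.6, a ratio of 2.60. patA, which encodes putrescine aminotransferase, read 1041.8 and 2166.8, a ratio of 2.08. All 3 stayed past 2-fold under the loess and quantile scalings, where csrB had a log2 ratio of 2.10 under each. On the poly-A scale their log2 ratios were 3.04, 2.95 and 2.55. No gene under the floor in the wild type reached 2-fold above it in the mutant.

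Among genes measured on both arrays, yodC, whose function is not characterised, had the lowest ratio, with signals of 2810.9 in the wild type and 646.2 in the mutant (4.35-fold lower). bsmA, a gene linked to biofilm stress tolerance, was 2.87-fold lower. gadE, the central activator of glutamate-dependent acid resistance, was 2.85-fold lower, at 2858.8 and 1001.6. rpsP, for ribosomal protein S16, was 2.85-fold lower. gadB, a glutamate decarboxylase gene, was 2.71-fold lower, at 8750.3 and 3223.1. The others of the 12 lowest were stable RNAs: the rRNA genes rrsA, rrsC, rrlE, rrlH and rrlG, from 2.63-fold to 2.83-fold lower, the small RNA ssrS (2.75-fold) and the transfer-messenger RNA ssrA (2.66-fold). The rRNA copies are near-identical and their probe sets are shared, so that they are not independent observations. Over the 12 measured rRNA genes the ratios ran from 1.60-fold to 2.83-fold lower, beside 2.35-fold for the poly-A controls. After loess rrsA had a log2 ratio of -0.36 and gadB of -0.72, whereas yodC (-1.85), rpsP (-1.27), gadE (-1.19) and bsmA (-1.15) stayed past 2-fold. The 8 genes that were 2-fold lower on the deposited scale and under both loess and quantile normalization were these 4, ymgB, fumC, sdhC and apaG, the last named after its values were seen. fumC, the fumarase of the SoxRS response, was under the floor in the mutant and at least 2.35-fold lower. On the poly-A scale yodC was at -1.90, sdhC at -1.31 and rpsP at -1.01. gadE (-0.76), bsmA (-0.67), fumC (-0.78) and apaG (-0.86) did not reach 2-fold there.

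Of the gene lists fixed beforehand, 23 had at least 4 measured members and 3 of them stood apart from signal-matched random lists, where 1.15 would do so by chance if genes were independent. Genes of an operon are not, and the number expected with such ties was not worked out; in simulated data without them, 4 of 50 unshifted lists were called apart. Ribosomal protein genes stood lowest. Of 51 measured members 14 were at least 2-fold lower, none was 2-fold higher and 37 were within 2-fold, and the median log2 ratio was -0.51, at percentile 0.04. rpsP, rplX (4755 in the wild type and 1944.6 in the mutant), rpsN (3158.3 and 1342.9) and rplR (3314.4 and 1416.1) had the lowest ratios, but 13 members had a ratio above 1. Of the 14 lower members 9 belong to 1 operon, spc. Of the 13 with a ratio above 1, 11 belong to its neighbour, the S10 operon. These operons were looked up after the data were seen. The counts and the percentile thus rest largely on few transcription units. The count of lower members rested on the scale: only rpsP stayed 2-fold lower after loess, after quantile normalization or on the poly-A scale, where 1, 1 and 12 members were 2-fold higher, rpsJ among them each time (named after its values were seen). The list's median was -0.32 after loess, below every one of the random lists. On the poly-A scale its sign turned, to 0.31, against 0.59 for all genes, below all random lists drawn on that scale.

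The flagella and chemotaxis list, the motility apparatus, had 21 of 32 measured members with a ratio above 1 and none past 2-fold, with a median log2 ratio of 0.14 at percentile 99.0. Of the 32 members 14 were bounds. Most of these were measured only through the mutant array, so their ratios could not lie below 1. The direction of the list is thus partly fixed by the floor. Nearly all members had signals less than 2-fold over the floor on both arrays, so that a 2-fold call was not possible for them. tar, the aspartate chemoreceptor gene, read 446.9 and 603.2. flhC, part of the master regulator of flagellar genes, read 356.5 and 557.6, at least 1.32-fold higher. flgK, a hook-filament junction gene, read 301.2 and 546.7, at least 1.30-fold higher. The kinase gene cheA went the other way, at 693.9 and 540.1, though its log2 ratio turned to 0.095 on the poly-A scale. These signals lay close to the floor, and the position depended on it: with both arrays required over the floor the median was 0.057 at percentile 69.1, and with the floor at the 75th percentile of signals it was -0.032 at percentile 20.2.

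Acid resistance genes had lower signals in the mutant in 14 of 17 measured members, and 3 of them were at least 2-fold lower. These were gadE, gadB and gadA, the second glutamate decarboxylase gene, which was 2.21-fold lower at 3089 and 1400.6. hdeB, a periplasmic acid chaperone gene, was 1.91-fold lower at 4044.6 and 2112.4. cadA, the acid-induced lysine decarboxylase gene, had the highest ratio of the list, with a log2 ratio of 0.47; it was named after its values were seen. The list's median of -0.26 stood at percentile 13.8 of lists matched on signal, so that the list as a whole did not stand apart. Against lists not matched on signal it was at percentile 0.26. After loess gadA had a log2 ratio of -0.76 and hdeB of -0.46, and on the poly-A scale gadA was at -0.18 and hdeB at 0.14, with its direction turned.

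The heat shock, RpoS, oxidative stress and SOS lists had medians below 0 on the deposited scale but did not stand apart from genes of like signal. All 15 measured heat shock genes had lower signals in the mutant, 2 of them by at least 2-fold: groS, the co-chaperonin gene, 2.43-fold, and htpX, a membrane protease gene, 2.22-fold. Their median was -0.34 at percentile 13.9, beside the 2.35-fold lower poly-A controls, and on the poly-A scale the chaperone gene dnaK turned to 0.43. Of 16 RpoS-dependent general stress genes 2 were at least 2-fold lower, sra (2.36-fold) and dps (2.08-fold), the latter encoding the starvation DNA-binding protein, and the median was -0.42 at percentile 32.4, with its sign turned to 0.15 (percentile 92.6) after loess and 0.14 (percentile 94.0) after quantile normalization. dps was at -0.11 after loess and turned to 0.13 on the poly-A scale. Of 18 oxidative stress genes only fumC passed 2-fold, and the median was -0.20 at percentile 12.5. The SOS list had a median of -0.14 at percentile 5.52, and the cold shock list of 0.046 at percentile 79.9, with none of the 12 and 7 measured members past 2-fold. In both lists most members had no signal 2-fold over the floor on either array, so for them no 2-fold call was possible.

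In central metabolism the TCA cycle list had 14 of 16 members with a ratio below 1 and 2 past 2-fold: sdhC, for a membrane subunit of succinate dehydrogenase, 2.59-fold lower at 1291.2 and 497.9, and icd, for isocitrate dehydrogenase, 2.19-fold lower. The median was -0.26 at percentile 8.67. sdhC stayed past 2-fold after loess (-1.27) and on the poly-A scale (-1.31). icd did not, at -0.89 after loess and -0.43 on the poly-A scale. ATP synthase and aerobic respiration genes had a median of -0.14 at percentile 20.9, with nuoA, of NADH dehydrogenase, 1.89-fold lower. Anaerobic respiration and fermentation genes (median 0.0044, percentile 33.4), alternative carbon genes (0.017, percentile 63.6), iron acquisition genes (-0.16, percentile 3.84), phosphate starvation genes (0.12, percentile 91.2), sulfate assimilation genes (-0.040, percentile 20.8), amino acid synthesis genes (0.13, percentile 93.7), nucleotide synthesis genes (-0.0010, percentile 34.4) and phage shock genes (0.014, percentile 79.9) held no member past 2-fold. The floor largely fixed this outcome. In each of these lists except phage shock, most measured members had no signal 2-fold over the floor on either array. For such members no 2-fold call was possible. In the nucleotide list only guaB (1011.1 in the wild type) could pass, and in the phosphate list only pstB (888.5 in the mutant). The acetolactate synthase gene ilvB had the highest ratio of the amino acid list, at 1075.6 and 1837.2, a ratio of 1.71 that passed 2-fold after loess (log2 ratio 1.05).

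No measured member of the lists of biofilm structure and signalling passed 2-fold, bsmA (2.87-fold lower) being in none of them. For the exopolysaccharide, fimbrial and curli lists the floor fixed this outcome. Their highest signals on either array, 710.5, 670.4 and 557.7, were not 2-fold over the floor, so no 2-fold call was possible. Only 10 of 19 exopolysaccharide genes and 5 of 10 fimbrial and Ag43 genes were measured. Whether these lists hold changes of 2-fold was thus not tested. Most measured members of the biofilm regulator and AI-2 list and of the indole and tryptophan list also had no signal 2-fold over the floor. The 13 measured biofilm regulator and AI-2 genes had a median of -0.18 at percentile 12.6. bhsA, a stress-induced outer membrane protein gene that influences biofilm formation, read 854.9 in the wild type and 1308.9 in the mutant, and the biofilm regulator gene bssR 7533.4 and 4524.4. The ratio of bssR was close to 1 after loess (log2 ratio 0.026) and its direction turned on the poly-A scale (0.44). Exopolysaccharide genes (median 0.10, percentile 79.0, 10 measured) and type 1 fimbriae and Ag43 genes (median 0.22, percentile 94.3, 5 measured) lay above 0. The adhesin gene fimH read 362.8 and 670.4, at least 1.59-fold higher. Bounds made up 5 of these exopolysaccharide genes and 4 of these fimbrial genes. A gene measured only through the mutant array cannot have a ratio below 1. This holds for every fimbrial bound and most exopolysaccharide bounds, so the direction of these lists is partly fixed by the floor. Only 3 of 7 curli genes were measured, and csgA, the curlin subunit gene, read 481.2 and 557.7. The indole and tryptophan list had a median of -0.076 at percentile 29.1, and mtr, a tryptophan and indole transporter gene, was 1.80-fold lower.

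**Figure D2:**
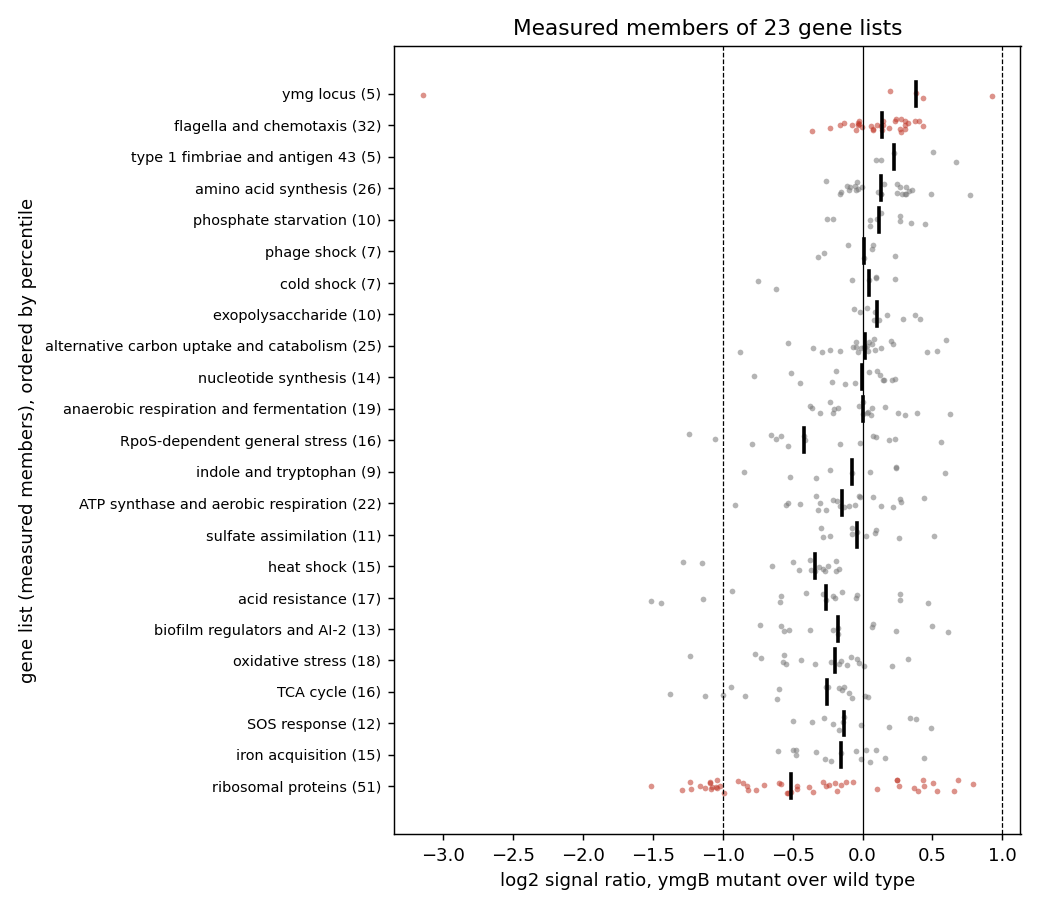
Each point is the log2 signal ratio (ymgB mutant over wild type, horizontal axis) of 1 measured gene in 23 gene lists (rows, with the number of measured members), black bars mark medians and dashed lines 2-fold; lists are ordered by percentile among signal-matched random lists, and the 3 that stood apart are red. Ribosomal protein genes (median -0.51) spread from -1.51 to 0.79, and in the ymg locus only ymgB lies below 0.

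Sequences that BW25113 lacks gave the background. The genotype of this strain carries deletions in araBAD, rhaBAD and lacZ. araA read 57.9 in the wild type and 13.6 in the mutant, rhaA 20.9 and 37.6, araB 85.9 and 65.3, and rhaB 160.1 and 121.2, all far under the floor. araD, rhaD and lacZ read between 517.4 and 625.1 on both arrays, and the place of their probes relative to the ends of the deletions was not analysed here. The 59 probe sets for phage, plasmid and transposon sequences outside the K-12 chromosome had medians of 12.1 in the wild type and 7.0 in the mutant.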

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

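The tests in this part were chosen after the results were seen. Outside the gene comparison, the median intergenic signal was 315.9 on the wild-type array and 360.8 on the mutant array, far above the medians of 12.1 and 7.0 for the 59 probe sets of phage, plasmid and transposon sequences. Non-specific hybridization would give absent sequences a like signal, but their median was 3.83% of the intergenic median in the wild type and 1.94% in the mutant (the higher ratio is 0.0383), and the deleted ymgB read 4.6. The deleted genes of BW25113 were mixed: araA, araB and rhaA read below 90 on both arrays, rhaB read 160.1 and 121.2, and araD, rhaD and lacZ lay above the intergenic medians, at 517.4 to 625.1, which is undecided without the ends of the deletions. Chromosomal DNA left after the DNase step and low-level transcription of the whole chromosome are both possible explanations; both need the same values here, and no test separated them.

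The poly-A controls had a median log2 ratio of -1.23, and all 12 probe sets were lower on the mutant array. This bears on the excess of lower genes (59 against 3). If array scaling was set by the signal that fills most probe sets, and this signal was larger relative to RNA in the mutant sample, then RNA of fixed input should come out lower, as the controls at -1.23 do. Of the other control probe sets, BioB-5 read 951.3 and 988.9 (log2 ratio 0.056) and BioC-3 74.5 and 101.8 (0.45); E. coli carries bioB and bioC itself, so what these measured here is not known. Whether the lower genes also fell relative to the added RNA was not decided: the comparison made is void, because the 58 lower genes other than ymgB were chosen for ratios past 2-fold, which largely sets how near their median lies to that of the controls (difference -0.253 after subtraction of the intergenic median). The amount of control RNA added per sample is not given in the sources used here, and an effect of ymgB on RNA content was not tested.

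Among 1099 measured intergenic probe sets without a gene name, 1 was at least 2-fold higher and 14 at least 2-fold lower in the mutant. The higher one had a log2 ratio of 1.69, with signals of 439.4 and 1414.7, and was not placed on the genome here.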

How the results depend on the processing

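The ymgB ratio kept its direction and stayed past 2-fold in every alternative that measured it. The alternatives with subtraction of the intergenic median were chosen after seeing the data. With 1 array per strain no replicate could be left out. No paired analysis was possible because each strain has 1 array. The 3 higher genes were kept in all scalings. Counts of higher and lower genes were 9 and 10 under quantile normalization, 10 and 8 under loess, 42 and 186 at 1.5-fold, 1 and 2 at 3-fold, 10 and 152 with the intergenic median subtracted, and 381 and 4 when that was also scaled on the poly-A controls; without a floor 29 were higher. Of the 59 lower genes, 10 remained under quantile normalization and 8 under loess. The share of higher genes among those past 2-fold was 4.84% on the deposited scale, 47.4% under quantile normalization and 55.6% under loess. Quantile normalization and loess balance the ratios at each signal level by construction. The share was 99.0% on the poly-A scale, where 1 factor raises the mutant array after the intergenic median is subtracted. None of these shares tests the excess. Among list medians, the flagella and chemotaxis list was at 0.057 (percentile 69.1) with both arrays over the floor, at -0.032 (20.2) with the floor at the 75th percentile, at -0.14 (39.2) with the intergenic median subtracted and at 0.33 (83.0) on the poly-A scale. On that scale the ymg locus was at 0.32 (50.8), ribosomal proteins at 0.31 (still the lowest percentile), sulfate assimilation at 0.44 (98.7), the TCA cycle at 0.26 (0.18), phosphate starvation at 1.17 (99.0) and amino acid synthesis at 0.93 (97.9), and dps turned to 0.13. Lists that stood apart under an alternative but not in the main analysis were, against unmatched lists and at their main medians, acid resistance (-0.26), RpoS-dependent general stress (-0.42), oxidative stress (-0.20), heat shock (-0.34), the TCA cycle (-0.26) and amino acid synthesis (0.13). The TCA cycle also did so under quantile normalization (-0.20), with the floor at the 75th percentile (-0.60) and with both arrays over the floor (-0.43); oxidative stress with the floor at the 75th percentile (-0.39); phosphate starvation with both arrays over the floor (0.20); type 1 fimbriae and Ag43 with the floor at the 25th percentile (0.42) and with none (0.46); and amino acid synthesis with the floor at the 25th percentile (0.19), at the 75th (0.23), with none (0.25) and with the intergenic median subtracted (0.087), whereas with both arrays over the floor its median was -0.020 (percentile 49.9). The RpoS list turned to 0.15 under loess and 0.14 under quantile normalization without standing apart, and anaerobic respiration and fermentation to -0.18 with both arrays over the floor. The ribosomal protein list stood apart under every alternative. The cause of these list changes was not tested. Single named genes gave 791 values on their side of the threshold under the alternatives fixed beforehand, 35 that dropped below it and 5 that passed it. No named gene past 2-fold changed sign under these, but among those within 2-fold bssR turned to 0.026 under loess, and cspE from -0.62 to 0.17 under loess and 0.017 under quantile normalization. Signal over the intergenic background limits what can be seen: ratios of genes near the floor are compressed.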

Other observations

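The genes and operons in this part, and their tests, were chosen after the data were seen. csrB was 3.07-fold higher in the mutant. csrA, for the regulator that csrB sequesters, read 3521.3 in the wild type and 3449.9 in the mutant, a ratio of 0.98, which turned to a log2 ratio of 0.51 after loess, where csrB was at 2.10. uvrY, for the response regulator that activates csrB, read 867.9 and 789.2, a ratio of 0.91, and had a log2 ratio of -0.027 after loess. glgS, a surface composition regulator gene, was 1.92-fold lower on the deposited scale and at a log2 ratio of -0.038 after loess. After loess, genes higher by at least 2-fold included ycgZ, fbaA (fructose bisphosphate aldolase, log2 ratio 1.16), ilvB (1.05), ilvN (1.05), the cold shock family gene cspC (1.06), the insertion sequence gene insF2 (1.06) and rpsJ (1.19) beside csrB, hisL and patA. The high signal at hisL did not extend along the histidine operon: hisG, the next gene, had a ratio of 1.20, and hisD was not measured.

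The S10 and spc operons, neighbours that hold ribosomal protein genes, went opposite ways. Most measured ribosomal protein genes outside these 2 operons had a lower signal in the mutant. All 11 genes of the S10 operon (rpsJ to rpsQ) had a higher signal in the mutant, with a median log2 ratio of 0.44 and a range of 0.11 to 0.79. Of these, rpmC was a bound. All 12 genes of the spc operon (rplN to rpmJ) had a lower signal, with a median of -1.05 and a range of -1.29 to -0.47. They include secY, which is not a ribosomal protein gene. On the deposited scale 9 of the 12 were at least 2-fold lower, and after loess 0 were. Signal-dependent compression of the mutant array would need the gap between the operons to shrink once the trend is removed. The difference of the medians was 1.49 on the deposited scale and 1.32 after loess, which argues against that trend as the whole explanation. On the poly-A scale, the S10 operon had a median of 1.75 and the spc operon of -0.015, so which operon departs from an unchanged level depends on the scale. Whether loss of ymgB or any other difference between the cultures did this cannot be told apart with 1 array per strain, at a difference of 1.49.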
